A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

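The series holds 6 Affymetrix YG_S98 arrays of the baker's yeast strain T128, 2 before fermentation, 2 at 15 min, 1 at 30 min and 1 at 60 min in liquid fermentation medium. Per the labels' protocols, cells from an 18 h fed-batch pre-cultivation were put into the medium at 30 °C, and poly(A) RNA was purified from hot-phenol extracts. The deposited values are linear probe set intensities, made with MAS 5.0 per the submitters' processing notes. The scaling setting is not given in the sources used here. In the values the 2%-trimmed mean per array ran from 15.7 to 337, so no common target was apparent, and no detection calls were used. All group and replicate assignments were taken from the sample titles.

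Each array was divided by its mean intensity after trimming 2% of the probe sets at each end and multiplied by the mean of the 6 trimmed means, 163.504, with control probe sets left out. The scaling factors were 0.485 and 10.4 before fermentation, 0.861 and 4.46 at 15 min, 1.21 at 30 min and 0.612 at 60 min. A pseudocount of 5% of the common mean (8.18) was added and log2 taken, so changes are on the log2(value + pseudocount) scale and understate the change of dim genes. Of the 9335 probe sets, 60 are controls, 6504 name 1 gene, 328 name several and 2443 are unnamed here. Only probe sets with 1 gene entered the comparisons, and probe sets of several genes, which include MAL32, TDH2, TEF1 and most histones, were not analysed here as genes. All 6504 matched the reference gene table by gene identifier. The 315 genes with several probe sets were averaged on the log2 scale, and at 15 min the probe sets of 136 of the 304 such genes tested differed in sign. Of 5656 genes, the 5361 whose mean scaled intensity reached 10% of the common mean were tested. That mean includes the arrays multiplied by 10.4 and 4.46, so low readings there count heavily toward passing this filter.

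Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), in 1 fit over all 4 groups, with Benjamini-Hochberg adjustment over the 5361 genes and a threshold of 0.05. With 2 residual degrees of freedom the prior degrees of freedom were infinite, so every gene carries the common SD of 1.20 and the test ranks genes by size of change. The comparisons were 15, 30 and 60 min against before fermentation and 60 against 15 min. The 3 comparisons with before fermentation share those control arrays, so no overlap between them was counted. The lone arrays at 30 and 60 min were assumed to vary like the replicated groups. There were 40 gene lists written from textbook knowledge, of whose members 917 matched a single-gene probe set and 48 did not. They were tested with camera in limma, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 40 lists. With a preset correlation the p-values come from the spread between genes, not between arrays, so small ones do not show that a shift would recur on new arrays. As alternatives camera with an estimated correlation, camera on ranks and fry were run. An estimated correlation called 0 lists in every comparison (lowest adjusted p 0.312, 0.273, 0.249 and 0.418 in the order above), with 5, 6, 8 and 4 lists at an unadjusted p below 0.05. The test fry, which asks whether a list moves one way and does not compare it with other genes, also called 0 lists, with 8, 12, 10 and 3 at an unadjusted p below 0.05. Fry and the estimated correlation both draw their p-values from the 2 residual degrees of freedom, where passing over 40 lists needs a very large statistic. Their 0 calls therefore cannot tell whether correlation between genes accounts for the shifts. Percentiles among 10000 random lists of the same size, matched on mean expression in 20 bins, describe these arrays only.

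Before the data were examined, the design, the lists, the alternatives and a rule for the genes named were fixed. The rule takes, per comparison, the 6 largest increases and 6 largest decreases that passed and whose groups do not overlap, filled up with the largest that missed the threshold, then the 2 members with the smallest p of up to 8 called lists per direction, and a fixed set of 12 genes. Not every gene it takes is printed. Some called genes outside the rule, such as MAE1 (YKL029C) at 15 min, were named to complete counts. Alternatives covered quantile normalization, median centring, values as deposited, pseudocounts of 1% and 20%, no filter, a 50% filter, the brightest probe set per gene, eBayes with a trend and robust eBayes, leaving out each replicated array, a block for the number in the titles, a fit of 2 groups alone and a 2-fold rule without overlap. A change of sign between values that both missed the threshold was not counted as a reversal. Files were prepared in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

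The procedure was tested on simulated arrays of 5361 genes with the common SD of these data and 50 genes changed at each size. For 15 min against before fermentation it recovered 100% of log2 changes of 6 or -6 and 54% of changes of 4 or -4, and it called 0.317% of unchanged genes. For 30 min it recovered 84% at 6, 72% at -6, 28% at 4 and 32% at -4, and for 60 min 88%, 84%, 24% and 36% in the same order. A list shifted in the simulation was called and 0 other lists were. The simulated spread was independent between genes and equal on all arrays, unlike the dim and bright arrays here. The simulation therefore does not show how often lists or genes are called falsely in these data.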

Results

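Gene expression was measured in a commercial baker's yeast, Saccharomyces cerevisiae T128, at the start of a model of dough fermentation. Cells in stationary phase from an 18 h fed-batch culture were moved into liquid fermentation (LF) medium, which stands in for dough, and fermented at 30 °C. The data are 6 arrays in 4 groups: 2 arrays of cells before fermentation, which serve as the control, 2 arrays after 15 min, 1 array after 30 min and 1 array after 60 min. Each array is an Affymetrix YG_S98 yeast array, hybridized with target made from poly(A) RNA. The number of arrays limits the precision of every value, and the arrays at 30 and 60 min have no replicate. Nothing states that the 2 arrays of a group came from separate cultures. The p-values of limma thus measure only the spread between these samples, which may be technical. Camera with its preset correlation takes its p-values from the spread between genes, so small ones do not measure the spread between arrays.

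The arrays numbered 2 in the replicated groups were much dimmer than the others. The trimmed mean intensity over probe sets was 337 and 15.7 on the 2 arrays before fermentation and 190 and 36.7 on the 2 arrays at 15 min, against 135 at 30 min and 267 at 60 min. Array 1 was thus 21.5-fold brighter than array 2 before fermentation and 5.17-fold brighter at 15 min. The share of probe sets above an intensity of 100 was 3.43% on array 2 before fermentation and 10% on array 2 at 15 min, against 24.9% to 48.7% on the other arrays. The 3′ to 5′ intensity ratio of ACT1, the actin gene, was 7.58 and 28.3 on these dim arrays and 1.23 to 1.47 on the other 4. The same ratio of SPT15, which encodes the TATA-binding protein, was 10.5 and 157 on the dim arrays and 4.16 to 5.83 on the others. On the dim arrays the 5′ intensities were low, at 17.8 and 19.3 for ACT1 and 2.7 and 3.4 for SPT15, against median probe set intensities of 9.1 and 16.1, so the size of these ratios is uncertain. The ratio of SRB4, a Mediator subunit gene with low signal, went the other way, at 1.07 and 1.58 on the dim arrays and 2.55 to 5.24 on the others, with 3′ intensities of 3.0 and 23.0 on the dim arrays. Across probe sets within pairs of arrays, Spearman's rho was 0.475 between the arrays before fermentation, 0.618 between those at 15 min and 0.922 between array 1 at 15 min and the 30 min array. Each array before fermentation correlated more with the same-numbered array at 15 min (0.74 for array 1, 0.52 for array 2) than with its own replicate. Array 1 at 15 min did likewise (0.74 against 0.618), while array 2 at 15 min went the other way (0.52 against 0.618). These correlations are across probe sets, which are not independent replicates. The ribosomal RNA control probe sets also differed: the 18S control 18srRnaa read 2088, 915 and 664 on array 1 before fermentation, array 1 at 15 min and the 30 min array. It read 40.6 and 12.6 on the dim arrays and 3.2 at 60 min. Array 1 of each replicated group and the lone arrays at 30 and 60 min are called the bright arrays here.

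**Figure D1:**
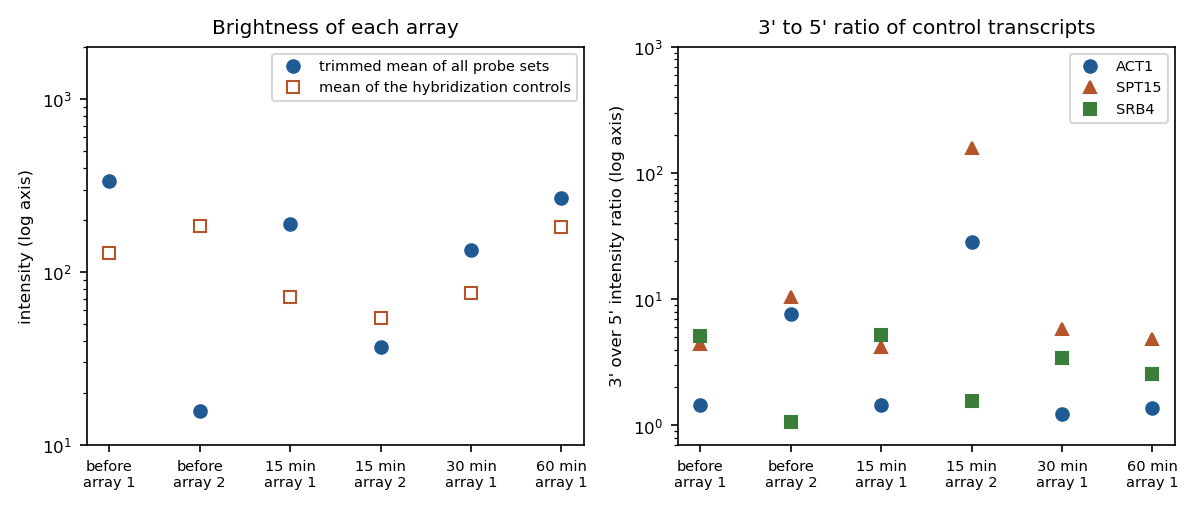
Left, for each of the 6 arrays, trimmed mean intensity over all probe sets and geometric mean of 9 hybridization controls, on a log axis, where array 2 before fermentation (15.7) and array 2 at 15 min (36.7) lie lowest for the trimmed mean. Right, ratio of 3′ to 5′ probe set intensity on a log axis, highest on the same dim arrays for ACT1 and SPT15 and lowest there for SRB4.

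After 15 min in the fermentation medium, lists of genes for making ribosomes and proteins shifted up, and lists for using non-fermentable carbon, for reserve carbohydrates and for stress protection shifted down, in camera with a preset correlation. None of these lists passed with an estimated correlation (lowest adjusted p = 0.312) or with fry (0.204). With 2 residual degrees of freedom behind them, those tests could hardly pass any list, so this does not decide whether the shifts hold. The same limit applies to them in every later comparison. Of 5361 genes tested with limma, 7 rose and 13 fell at an adjusted p below 0.05. The genes that rose were HXT1 (YHR094C), a low-affinity glucose transporter, ANB1 (YJR047C), a translation factor of the hypoxic gene set, YDR222W, MCH5 (YOR306C), a riboflavin transporter, AAH1 (YNL141W), adenine deaminase, RPL36A (YMR194W), a ribosomal protein, and MAE1, the mitochondrial malic enzyme. HXT1 rose by 5.36 on the log2 scale (SE 1.20, limma adjusted p = 0.0142, 2 arrays against 2), from scaled intensities of 36.5 and 259.6 to 2932 and 6824. ANB1 rose by 5.30 (adjusted p = 0.0142), YDR222W by 5.21 (0.0159), MCH5 by 4.77 (0.0326), AAH1 by 4.67 (0.0352), RPL36A by 4.64 (0.0352) and MAE1 by 4.58 (0.0397). RPL36A and ANB1 have near-identical copies, RPL36B and HYP2, so their signal is uncertain between copies. Within the bright pair and within the dim pair the change was 6.04 and 4.67 for HXT1, 3.95 and 6.66 for ANB1, 3.72 and 5.62 for AAH1 and 2.35 and 6.92 for RPL36A.

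The largest decrease was that of RGI2 (YIL057C), a gene of respiratory growth, which fell by 6.61 on the log2 scale (SE 1.20, limma adjusted p = 0.000222), from 1348 and 3151 to 20.5 and 7.58. Its relative RGI1 (YER067W) fell by 5.15 (adjusted p = 0.0172). PEP12 (YOR036W), an endosomal membrane fusion protein, fell by 5.68 (0.00648), and so did SIP4 (YJL089W), an activator of gluconeogenic genes (-5.02, 0.0211), YIG1 (YPL201C; -5.01, 0.0211) and ECM4 (YKR076W), a glutathione transferase (-4.82, 0.0326). TPS1, the trehalose-6-phosphate synthase, fell by 4.74 (0.0326), and JEN1, the lactate and pyruvate transporter, fell by 4.71 (0.0327). The other genes that fell were FMP16, EIS1, TMA10, ATG39 and NRS1. Within the bright pair and within the dim pair the change was -5.56 and -7.65 for RGI2 and -6.63 and -3.66 for RGI1. Among all 5361 genes, 66.6% had the same sign within the bright pair and within the dim pair.

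Of 40 gene lists fixed before the data were examined, 9 were shifted up and 9 down at 15 min by camera with its preset correlation of 0.01. The median change of all genes was -0.35 on the log2 scale, and list medians are not corrected for it except where stated. The 109 measured ribosome biogenesis genes had a median change of 1.96, which is 2.31 relative to all genes (camera adjusted p = 1.7e-28), and 94 of them were higher in both pairs. Of these 109, 21 passed when adjusted over the list alone and 0 over all genes. DHR2, an RNA helicase of small subunit maturation, had a change of 4.13 (adjusted p = 0.0722) and UTP13 of 4.12 (0.0722). The 81 cytosolic ribosomal protein genes had a median of 2.03 (3.8e-26), with 69 higher in both pairs, 9 passing when adjusted over the list alone and 1, RPL36A, over all genes. All 18 cytosolic tRNA synthetase genes were higher in both pairs, with a median of 2.42 (2.7e-10). The 25 genes of RNA polymerases I and III had a median of 1.59, the 23 of sulfur assimilation and methionine 1.88, the 18 of branched-chain amino acids and lysine 1.60, the 19 of purine synthesis 1.44, the 27 translation factors 1.13 and the 21 of histidine and aromatic amino acids 0.86. Among their members, MET16 had a change of 3.09, the branched-chain aminotransferase gene BAT1 of 3.93 and GUA1, GMP synthase, of 3.28, none of which passed over all genes. The medians of these 9 lists ran from 1.30 to 2.38 within the bright pair and from 0.61 to 2.63 within the dim pair, and the bright median of purine synthesis, 1.40, stood at the 82.4th percentile of 10000 random lists of like expression. With an estimated correlation between genes none of these lists passed, and their adjusted p ran from 0.312 to 0.727.

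The lists that shifted down at 15 min were led by gluconeogenesis and the glyoxylate cycle, whose 17 genes were all lower in both pairs, with a median of -3.04 (camera adjusted p = 1.1e-11). Of these 17, 11 passed when adjusted over the list alone and 2, SIP4 and JEN1, over all genes. The 31 general stress response genes had a median of -2.42 (1.7e-09), and 28 were lower in both pairs. OM45, a mitochondrial outer membrane protein, had a change of -4.03 and GPX1, a glutathione peroxidase, of -3.84. Medians were -2.50 for 16 genes of fatty acid beta-oxidation, -2.24 for 13 of glycogen metabolism, -2.51 for 14 of the tricarboxylic acid cycle, -1.45 for 31 of the respiratory chain and ATP synthase and -2.82 for 7 of trehalose metabolism. They were -1.75 for 16 genes of autophagy and -1.41 for 31 of the proteasome. Among the lists that passed, the medians of the proteasome, stress response and respiratory lists differed most between the pairs, at -2.37 within the bright pair against -0.16 within the dim pair for the proteasome, -3.61 against -1.71 for stress response and -2.50 against -0.72 for respiration. Over the 9 lists the medians ran from -3.61 to -1.69 within the bright pair and from -2.99 to -0.16 within the dim pair. With an estimated correlation the adjusted p of these lists ran from 0.312 to 0.795.

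For genes of sugar breakdown itself the result at 15 min depended on single arrays. The 15 glycolysis genes had a median change of 0.67 and did not pass (camera adjusted p = 0.102), but they passed without array 2 at 15 min (1.91, 0.000166), without array 1 before fermentation (1.37, 0.00556), in values as deposited (0.0333) and with camera on ranks (0.0473). Between the bright arrays the glycolysis median was 0.98, at the 43.4th percentile of random lists. The 7 genes from pyruvate to ethanol had a median of 0.82 (0.280). PDC1, pyruvate decarboxylase, had a change of 0.93, ADH1, the fermentative alcohol dehydrogenase, of 0.35 and HXK2, hexokinase, of -0.14, with SE 1.20 for each. The sign of the ADH1 value turned under quantile normalization (-0.27) and that of HXK2 under quantile normalization (0.23) and median centring (0.35). ADH2, the glucose-repressed alcohol dehydrogenase, had a change of -2.36, PCK1 of -2.45, FBP1 of -1.61, SUC2, invertase, of -2.15 and HSP12 of -1.64, and none passed. The signals of ADH1, ADH2, PDC1 and SUC2 are uncertain between near-identical copies. ACT1 had a change of 0.34, which turned to -0.29 under quantile normalization. The 11 hexose transporter genes measured had a median of -0.80 and a mean of -0.06, while camera gave an upward direction that did not pass (0.736). The 7 genes of maltose and sucrose use had a median of -2.06 and did not pass (0.0822), but passed with the 50% filter (0.0222). Thioredoxin and glutathione genes had a median of -1.29 and did not pass with the main settings. They passed with camera on ranks (camera adjusted p = 0.0189), under quantile normalization (0.0237), with the 20% pseudocount (0.0259) and in some fits without a single array. Of the lists that stand for other cell states, meiosis and sporulation (0.782) and mating (0.629) did not pass, though mating passed downward without array 1 before fermentation (0.00761) and without array 2 at 15 min (0.0468).

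The gene counts at 15 min depended on single arrays. Higher and lower counts were 3 and 4 without array 1 before fermentation, 1 and 4 without array 2 before fermentation, 0 and 1 without array 1 at 15 min and 0 and 0 without array 2 at 15 min. Of the 20 genes called, 7, 4, 1 and 0 were still called in turn. Without array 1 at 15 min 5 lists were shifted up, and branched-chain amino acids and lysine (0.0783), histidine and aromatic amino acids (0.285), purine synthesis (0.0631) and translation factors (0.373) no longer passed. Without array 1 before fermentation the proteasome (0.661), respiration (0.425) and tricarboxylic acid cycle (0.109) lists no longer passed, and without array 2 before fermentation translation factors (0.0755) did not. Centring each array on its median turned the split of calls from 7 higher and 13 lower (35% higher) to 8 and 2 (80% higher). Quantile normalization left 0 and 1.

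**Figure D2:**
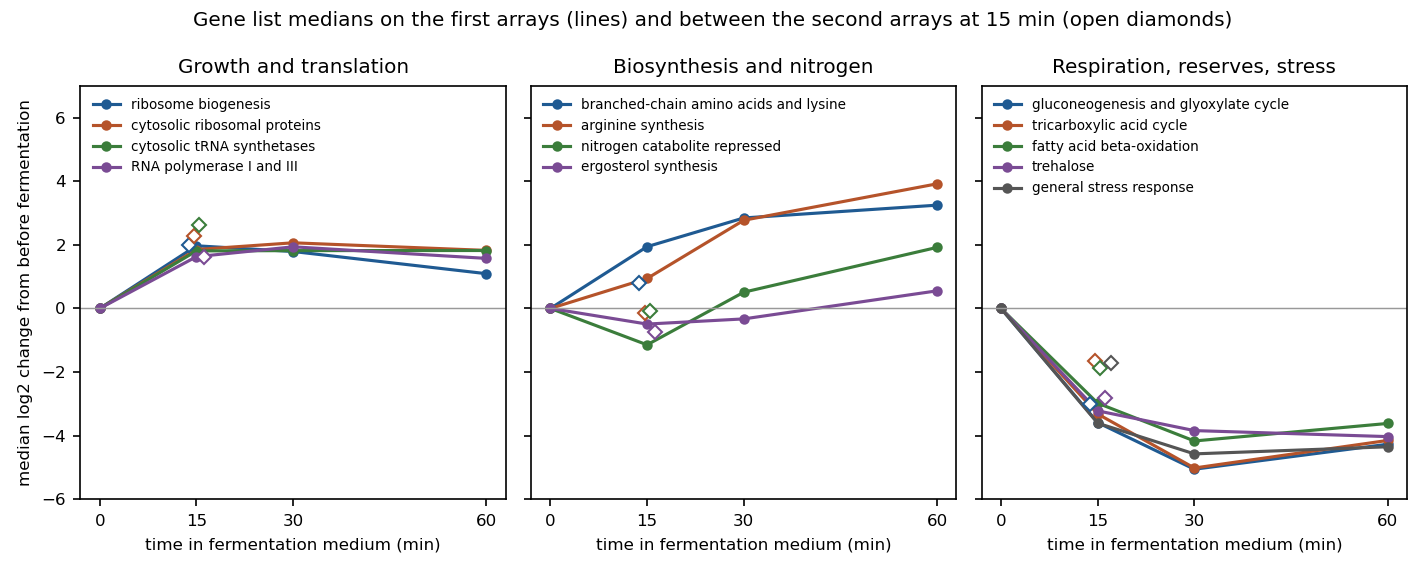
Median log2 change from before fermentation for 13 gene lists against time in minutes, where points joined by lines compare the bright arrays, with 1 array per time, and open diamonds give the change within the dim pair at 15 min. Ribosome biogenesis stood at 1.97 at 15 min and 1.09 at 60 min, the nitrogen catabolite repressed list went from -1.15 to 1.92, and the stress response list stood at -3.61, -4.58 and -4.35.

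At 30 min, 7 genes rose and 69 fell against before fermentation by limma (1 array against 2, SE 1.47 for each gene). The lone array is assumed to vary like the replicated groups. INA1 (YLR413W) rose by 5.91 on the log2 scale (limma adjusted p = 0.0208), MAE1 by 5.64 (0.0248), ANB1 by 5.57 (0.0258) and PRM7 by 5.33 (0.0330). DAL4, the allantoin transporter, rose by 5.25 (0.0361), BAT1 by 5.14 (0.0412) and ASP1, asparaginase, by 5.05 (0.0453). SIP18 (YMR175W), a desiccation stress protein, fell by 7.18 (0.00401), from 2257 and 4288 to 13.4. NRS1 (-6.98), SPG4, a gene of stationary phase (-6.94), MLS1, malate synthase of the glyoxylate cycle (-6.85), RGI2 (-6.81) and PEP12 (-6.77) also fell, each with an adjusted p of 0.00401. PCK1, phosphoenolpyruvate carboxykinase, fell by 5.18 (0.0397), from 2070.4 and 2397 to 53.3, and TPS1 fell by 5.03 (0.0463). HXT1 had a change of 3.96, HSP12 of -3.85 and FBP1 of -3.61, and none of these passed.

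Among the lists at 30 min, 13 were shifted up and 10 down by camera with the preset correlation, against a median change of all genes of -0.61. None passed with an estimated correlation (lowest adjusted p = 0.273). Ribosome biogenesis had a median of 2.11 (adjusted p = 1.9e-22), ribosomal proteins 2.41 (4.8e-22), tRNA synthetases 2.89, branched-chain amino acids and lysine 3.03 and purine synthesis 2.71. Translation factors had a median of 2.09, sulfur assimilation 2.53, RNA polymerases I and III 1.70, histidine and aromatic amino acids 2.34 and arginine synthesis 2.36, with all 8 arginine genes above 0. The glycolysis median was 1.83 (0.000625) and that from pyruvate to ethanol 1.32 (0.0235), but between the bright arrays these medians were 0.94 and 0.92, at the 36.8th and 50.8th percentiles of 10000 random lists of like expression. The nitrogen catabolite repressed list, genes for poor nitrogen sources, passed with a median of 0.27 (0.0302). It did not pass without array 2 before fermentation (0.0909), with camera on ranks (0.120), under quantile normalization (0.117) or with the 50% filter (0.275). The pyruvate to ethanol list did not pass without array 2 before fermentation (0.133), under quantile normalization (0.117) or with the 50% filter (0.109). Adjusted p over the 13 lists ran from 0.273 to 0.566 with an estimated correlation.

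The stress response list had the smallest p among the lists shifted down at 30 min, with a median of -3.83 (camera adjusted p = 5.5e-13). Of its 31 genes, 5 passed over all genes and 22 when adjusted over the list alone, among them GPX1, which fell by 6.49 (limma adjusted p = 0.00724). Gluconeogenesis and the glyoxylate cycle had a median of -4.75, with 5 of 17 genes passing over all genes, including MDH2, cytosolic malate dehydrogenase, which fell by 6.13 (0.0133). Beta-oxidation had a median of -3.70, where FOX2, its multifunctional enzyme (-6.45, 0.00731), and CTA1, peroxisomal catalase (-5.60, 0.0250), fell. The tricarboxylic acid cycle had a median of -3.80, where KGD1 fell by 5.34 (0.0326). Respiratory genes had a median of -3.11, where ATP7 of the ATP synthase fell by 5.44 (0.0276). The remaining lists were the proteasome (-2.64), glycogen (-3.44), autophagy (-2.54), trehalose (-3.47) and thioredoxin and glutathione (-2.18). With an estimated correlation the adjusted p of these 10 lists ran from 0.273 to 0.566. Counts of genes higher and lower were 6 and 19 without array 1 before fermentation and 2 and 82 without array 2, and without array 1 the thioredoxin list no longer passed (0.206). Median centring gave 7 and 6 (53.8% higher against 9.21%), and quantile normalization gave 0 and 0.

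At 60 min, 2 genes rose and 27 fell against before fermentation by limma (1 array against 2, SE 1.47). LYS9, a lysine synthesis enzyme, rose by 5.62 on the log2 scale (limma adjusted p = 0.0401), from 37.7 and 28.1 to 2000.3, and INA1 by 5.46 (0.0442). MAE1 (5.33, adjusted p = 0.0526), ANB1 (5.26, 0.0544), AAT1 (5.18, 0.0554) and DAL4 (5.07, 0.0619) missed the threshold. SIP18 (-6.54), FOX2 (-6.47), YET2 (-6.40) and FMP16 (-6.31) fell, each with an adjusted p of 0.0253. RGI2 (-6.21, 0.0267), TMA10 (-6.12, 0.0267), CTA1 (-5.60, 0.0401) and GSY2, glycogen synthase (-5.44, 0.0443), fell as well. TPS1 had a change of -4.77 (0.0895), PCK1 of -4.38 (0.125) and HXT1 of 3.91 (0.189), and none passed.

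In the lists at 60 min, 15 were shifted up and 10 down by camera with the preset correlation, against a median change of all genes of -0.36. None passed with an estimated correlation (lowest adjusted p = 0.249). The largest medians upward were those of arginine synthesis (3.34, adjusted p = 3.4e-07), branched-chain amino acids and lysine (3.19, 2.6e-12), tRNA synthetases (2.59), histidine and aromatic amino acids (2.57), sulfur assimilation (2.34), purine synthesis (2.33) and ribosomal proteins (2.22, 5.9e-19). All 8 arginine genes were above 0, and 6 passed when adjusted over the list alone, though 0 over all genes. Ribosome biogenesis had a median of 1.43 (8.3e-12), nitrogen catabolite repressed genes 1.78, RNA polymerases I and III 1.51, thiamine and vitamin B6 genes 1.51 and ergosterol genes 0.80. Glycolysis (1.92), pyruvate to ethanol (1.66) and translation factors (1.82) also passed, but their medians between the bright arrays were 0.82, 0.85 and 0.66, at the 50.2nd, 59.9th and 70.9th percentiles of random lists. Medians of the lists shifted down were -3.74 for stress response (4.1e-16), -4.15 for gluconeogenesis, -3.23 for beta-oxidation, -3.18 for glycogen and -3.51 for trehalose. They were -2.95 for the tricarboxylic acid cycle, -2.52 for respiration, -1.93 for autophagy, -1.65 for the proteasome and -1.21 for thioredoxin and glutathione. With an estimated correlation the adjusted p ran from 0.249 to 0.558 for lists shifted up and from 0.249 to 0.617 for lists shifted down. Counts of genes higher and lower were 1 and 7 without array 1 before fermentation, 0 and 0 without array 2 before fermentation, and 0 and 8 without either array at 15 min. Without array 2 before fermentation, glycolysis (0.102) and pyruvate to ethanol (0.136) no longer passed, and without array 1 the proteasome (0.456) and thioredoxin (0.401) lists no longer passed. Pyruvate to ethanol also failed to pass under quantile normalization (0.0663) and with the 50% filter (0.0897), and ergosterol with that filter (0.0598). Median centring and quantile normalization each gave 0 and 0.

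**Figure D3:**
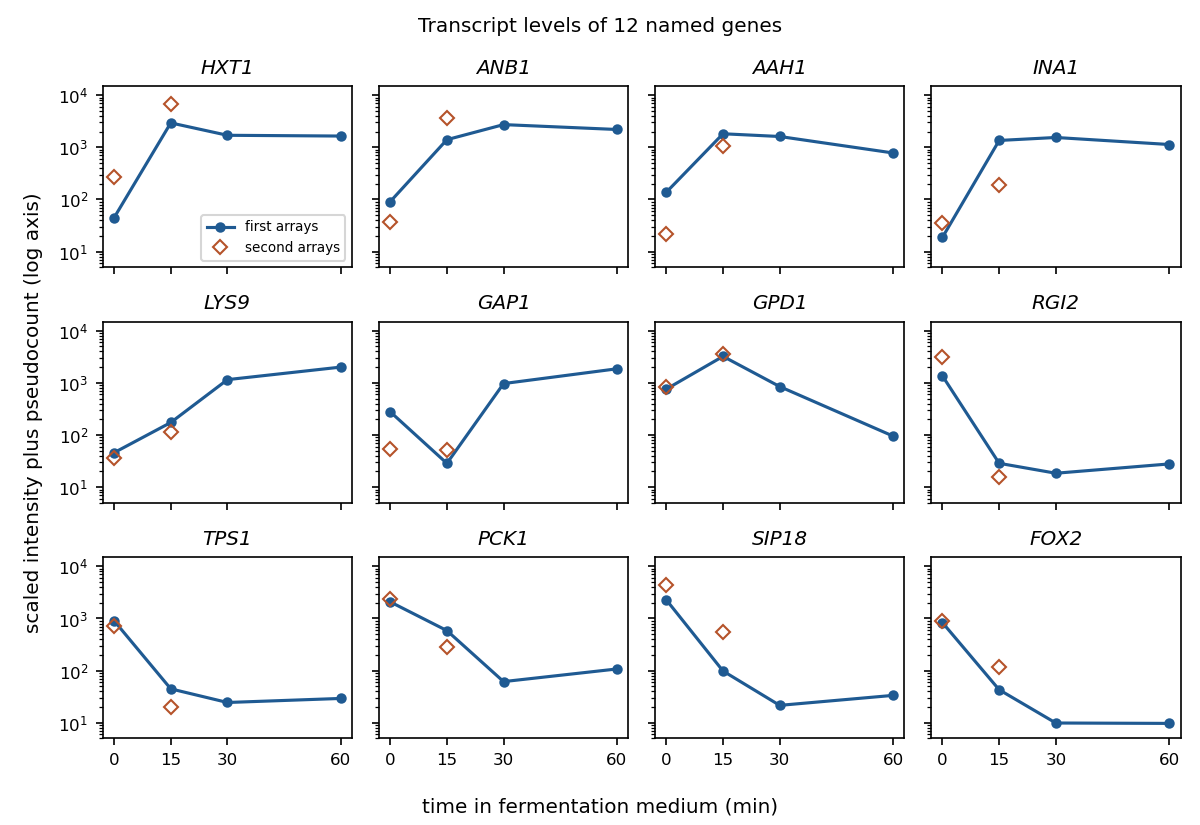
Scaled intensity plus the pseudocount of 8.18, on a log axis, of 12 named genes against time in minutes, where filled circles joined by lines are the bright arrays and open diamonds the dim arrays at 0 and 15 min. HXT1 rose from 36.5 to 2932 on the bright arrays between 0 and 15 min, GAP1 was lowest at 15 min, and RGI2, TPS1, SIP18 and FOX2 were lower on every array after the start than on both arrays before. The open diamonds are scaled up by 10.4 at 0 min and 4.46 at 15 min. Low ones, such as LYS9 at 0 min and RGI2 at 15 min, stand for readings below the median of their array.

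The comparison of 60 min with 15 min asks which genes went on changing within fermentation. No gene passed with limma (lowest adjusted p = 0.396), and 72 genes were higher and 33 lower at an unadjusted p below 0.05. The 6 largest values upward were GAP1, the general amino acid permease (5.62), OPT2 (5.46), DAL3 of allantoin use (5.44), ERG3 of ergosterol synthesis (4.98), RTC2 (4.95) and MEP2, an ammonium permease (4.56). GAP1 had scaled intensities of 20.4 and 42.3 at 15 min, 962 at 30 min and 1855 at 60 min. The largest values downward were GPD1, glycerol-3-phosphate dehydrogenase (-5.15), YHR138C (-4.80), CPP3 (-4.39), MRA1 (-3.94), the glycerol-phosphatase gene GPP2 (-3.80) and YLR146W-A (-3.50). All of these missed the threshold, and each carries an SE of 1.47 with 1 array against 2.

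Between 15 and 60 min 12 lists were shifted up and 6 down by camera with the preset correlation. None passed with an estimated correlation (lowest adjusted p = 0.418). The nitrogen catabolite repressed list had a median of 2.36 (adjusted p = 5.6e-18), with 9 of 23 genes passing when adjusted over the list alone and 0 over all genes. Between the bright arrays its median was 3.16. Arginine synthesis had a median of 2.96 (1.1e-11) with all 8 genes above 0, including ARG1 (4.41) and ARG4 (4.40). Ergosterol synthesis had a median of 1.56 (4.1e-09), with 22 of 24 genes above 0. Between the bright arrays the ergosterol median was smaller, at 0.77, which stood at the 99.98th percentile of random lists. Medians were 1.59 for branched-chain amino acids and lysine, 1.35 for histidine and aromatic amino acids and 1.25 for thiamine and vitamin B6. They were 0.93 for purine synthesis, 0.83 for G1 and S phase genes, 0.64 for anaerobic genes, 0.60 for fatty acid synthesis, 0.60 for translation factors and 0.45 for glycolysis. With an estimated correlation the adjusted p of these lists ran from 0.418 to 0.834. The stress response list shifted down further, with a median of -1.28 (1.0e-06), and ribosome biogenesis shifted down with a median of -0.68 (0.00467). Glycerol and osmotic response (-0.57), respiration (-0.84), hexose transporters (-1.04) and meiosis and sporulation (-0.93) also shifted down. With an estimated correlation the adjusted p of these 6 lists ran from 0.501 to 0.834. In values as deposited, where the median of all genes was 1.19 in place of -0.16, the medians of all of these downward lists except stress response were above 0, at 0.94 for ribosome biogenesis, and ribosome biogenesis (0.0857) and hexose transporters (0.0750) no longer passed.

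Several of these 60 min shifts rested on 1 array at 15 min. Without array 2 at 15 min the glycolysis median turned to -0.18, translation factors to -0.31 and meiosis to 0.080, and fatty acid synthesis (0.425) and purine synthesis (0.575) no longer passed. Without array 1 at 15 min, ribosome biogenesis (0.830), respiration (0.371), hexose transporters (0.279), glycerol and osmotic response (0.261), anaerobic genes (0.265) and G1 and S phase genes (0.474) no longer passed. Calls also ended for glycerol and osmotic response with camera on ranks (0.106), for meiosis under quantile normalization (0.0817) and with the 20% pseudocount (0.143), and for hexose transporters with the 50% filter (0.0821) and the 1% pseudocount (0.0706). The same held for translation factors with the 50% filter (0.118), the 20% pseudocount (0.0520) and quantile normalization (0.0556), for glycolysis with the 50% filter (0.0887) and for anaerobic genes with the 50% filter (0.050006) and the 1% pseudocount (0.0609).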

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

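List calls changed less with scaling than gene counts, in part by construction, since camera sets a list against other genes and a shift common to an array's genes nearly cancels. At 15 min all 18 lists kept their call and direction under quantile normalization, median centring, values as deposited and both pseudocounts, and 23, 25 and 16 of the 23, 25 and 18 lists in the later comparisons kept theirs in values as deposited, against 21, 24 and 16 under quantile normalization. Estimated correlation and fry each called 0 lists up and 0 down in every comparison, where 2 residual degrees of freedom left little room for any call. Of the 20, 76 and 29 genes called at 15, 30 and 60 min, 1, 0 and 0 were kept under quantile normalization and 9, 13 and 0 under median centring. The prior degrees of freedom, infinite with the settings used in the report, were 24.2 under quantile normalization, 51.2 under median centring, 20.2 with the 20% pseudocount and 14.5 with the 50% filter, which left 3178 genes. The cause of each change in count was not tested. The sign at 15 min was the same within the bright and the dim pair for 66.6% of the 5361 genes. It was the same for 75.6% of the 2509 genes at or above the trimmed mean on either dim array. Those genes were picked by the dim arrays, whose difference is the dim change, so the higher share does not isolate an effect of background.

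Counts of genes that moved, as higher and lower, were as follows at 15 min (7 and 13), 30 min (7 and 69) and 60 min (2 and 27). Quantile normalization gave 0 and 1, 0 and 0, 0 and 0, median centring 8 and 2, 7 and 6, 0 and 0, and values as deposited and the 50% filter 0 throughout. A pseudocount of 1% gave 3 and 8, 3 and 85, 0 and 34, and one of 20% gave 3 and 2, 3 and 16, 0 and 0. No filter gave 16 lower at 15 min, 86 lower at 30 min and 5 and 43 at 60 min, the brightest probe set 0 and 9 at 60 min, an intensity trend 34 and 108 lower at 15 and 30 min with 3 and 52 at 60 min, and robust eBayes 4 higher at 60 min. A fold of 2 without overlap gave 741 and 1222 at 15 min. Without the fold cut, 2259 of 5361 genes had no overlap, where chance alone leaves 33.3% of genes without overlap. At a fold of 4, chosen after seeing the data and without a test, all arrays gave 374 and 625 genes at 15 min and the bright arrays alone 505 and 1078, with 245 and 552 in both.

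Leaving out each array in turn gave 0 to 3 higher and 0 to 4 lower genes at 15 min, 2 to 6 and 19 to 82 at 30 min, 0 to 1 and 0 to 8 at 60 min, and 0 for 60 against 15 min. Lists numbered 5 to 10 up and 8 to 12 down at 15 min, 11 to 16 and 10 to 12 at 30 min, 14 to 16 and 10 to 11 at 60 min, and 8 to 12 and 3 to 9 for 60 against 15 min. In that last comparison the direction given by camera reversed for 4 lists. The glycolysis median ran from -0.18 to 1.36 and that of meiosis and sporulation from -1.85 to 0.080. Sulfur assimilation ran from -0.45 to 0.75 and translation factors from -0.31 to 1.34. The G1 and S phase median also changed sign, from 0.83 with all arrays to -0.055 without array 1 at 15 min, though its direction in camera did not. Sulfur assimilation, not shifted with all arrays, passed at -0.45 without array 2 at 15 min (camera adjusted p = 0.00815) and at 0.75 without array 1 at 15 min (0.00978). Other lists with medians below 0 gained a call there: the tricarboxylic acid cycle (0.00395), phosphate starvation (0.00340) and gluconeogenesis (0.0130) without array 2, and mating (0.00691) without array 1.

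The titles mark the second array before fermentation and at 15 min with a 2 and give the first array no number. Arrays are numbered 1 and 2 here by that mark, which coincides with the bright and the dim arrays. Same-numbered arrays deviated together with a correlation of 0.43. With that number as a replicate block, 170 genes were higher and 313 lower at 15 min, all 20 genes called without it among them. The list counts were 9 and 9 as without it. The block fit has 1 residual degree of freedom, and nothing states that same-numbered arrays are pairs.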

Other observations

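The tests of hybridization failure and of 3′ truncation were chosen after the array intensities were seen, and the others were set before their results. Values of 3 hexose transporter genes, chosen after they were seen, are given here. The list of 11 such genes did not pass with camera at 15, 30 or 60 min against before fermentation (adjusted p = 0.736, 0.762 and 0.346). HXT3, a low-affinity glucose transporter like HXT1, had scaled intensities of 249.9 and 171 before fermentation, 2668 and 1493 at 15 min, 1899 at 30 min and 659 at 60 min. HXT5, a transporter of slow-growing cells, had 2330.4 and 7829.7 before fermentation, 458 and 503 at 15 min, 54.1 at 30 min and 149 at 60 min, and its fall at 30 min passed (-6.10, limma adjusted p = 0.0134). HXT2, a high-affinity transporter, had 2418 and 737, then 370 and 258, then 1343 at 30 min and 72.8 at 60 min. None of the other changes of HXT2, HXT3 or HXT5 against before fermentation passed.

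The glycerol synthesis genes GPD1 and GPP2 read higher on both arrays at 15 min than on both before fermentation, while the list of 14 glycerol and osmotic response genes did not shift then (median -0.32, camera adjusted p = 0.629, 7 above 0). GPD1, chosen by the fixed rule, had scaled intensities of 753 and 834 before fermentation, 3219 and 3552 at 15 min, 842 at 30 min and 87.3 at 60 min. GPP2 had 108 and 43.8, then 2567 and 1029, then 1207 and 109. The change of GPP2 at 15 min was 4.40 (limma adjusted p = 0.0583) and that of GPD1 2.08 (0.492), so neither passed. On glycolysis, the glucose-phosphorylating genes HXK1 (-2.16) and GLK1 (-1.83) and the phosphofructokinase gene PFK1 (1.44) differed in sign at 15 min without passing.

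One pattern concerns the arrays themselves: array 2 of both replicated groups was dim. A failed hybridization or scan is argued against, since the 9 spiked hybridization controls kept ratios of array 2 to array 1 of 0.757 at 15 min and 1.42 before fermentation, while the trimmed means had ratios of 0.193 and 0.0465. The control probe set DapX-3, which is not among these 9, was lower on array 2. It read 175.4 and 2.3 on arrays 1 and 2 before fermentation and 158.0 and 7.2 at 15 min, and the reason was not tested. Target truncated toward the 3′ end is favoured by the ACT1 ratio, whose log2 value on the dim arrays lay at least 2.37 above every bright array: even dimming would give 5′ intensities of 144.5 and 411, where 17.8 and 19.3 were read. The SRB4 ratio was lower on the dim arrays (1.07 and 1.58) than on the bright ones (2.55 to 5.24), but even dimming would put its 5′ intensities at 0.726 and 0.734, so it decides nothing, and truncation stays open. A loss that grows with coding length is argued against across all genes, where Spearman's rho of dim minus bright with coding length was 0.136 before fermentation and -0.0306 at 15 min, but among the 1777 genes whose mean over array 1 of both groups exceeded the common trimmed mean, rho was 0.0184 and -0.224, so a length effect at 15 min stays open.

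The nitrogen and arginine lists were shifted up at 60 against 15 min by camera with the preset correlation, but not with an estimated one (adjusted p = 0.418 for both). A low 15 min mean made by the dim array is argued against, since on the bright arrays alone the nitrogen median of 3.16 stood at the 100th percentile of random lists. A shift confined to the 60 min array is argued against, since the 30 min median over 15 min, 1.20, also stood at the 100th percentile. Both medians subtract array 1 at 15 min, so they are not independent. From 30 to 60 min the nitrogen median rose by a further 0.74 (99.74th percentile), so a part particular to the 60 min array stays open. A loss of ribosomal RNA that shifts all lists alike could not be tested, since scaling had already removed most of such a shift. On the bright arrays the higher of the ribosomal protein and stress medians was -0.0762 (log2) against 3.16 for nitrogen. A shift alike in all lists would not by itself make that difference between lists. Relative to all genes the nitrogen median over all arrays stayed at 2.51 to 2.59 over 4 scalings, but largely by construction. Scaling and subtracting the median of all genes remove most of a shift common to an array, so those values decide nothing. No biological explanation was tested.

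The 4 arrays at 15 min and before fermentation can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 18 lists and 20 genes, 1 of the 3 splits reaching each count. The highest other split gave 15 lists and 0 genes. That split for lists set array 1 of both groups against array 2 of both groups, which follows the difference in brightness. Medians of the 9 lists shifted up ran from 1.30 to 2.38 within the bright pair and from 0.61 to 2.63 within the dim pair, and those of the 9 shifted down from -3.61 to -1.69 and from -2.99 to -0.16.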
